A study of Mus musculus with 18 samples.

How the data were processed

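Sorted lung epithelial cells of adult reporter mice, 8 to 12 weeks old, were profiled on Affymetrix arrays, with cells pooled from 3 to 4 animals. Per the labels' protocols, lungs taken with trachea and bronchi were dissociated with dispase, CD31 and CD45 positive cells were depleted on beads, EpCAM positive cells were enriched, and DAPI negative EpCAM positive cells were sorted by their level of green fluorescent protein. The fluorescent protein was driven by a TCF/Lef reporter of Wnt/beta-catenin signalling. From each sort 8 ng of total RNA was amplified and labelled with the WT Pico reagents of the manufacturer.

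The deposited values are log2 values of 72688 probe sets on 18 arrays, made by the authors with RMA (background correction, quantile normalization and a summary per probe set), per the submitters' processing notes. The software, its version, the chip library and the genome build are not given in the sources used here. No deposited value was negative, and the values ran from 1.79 to 19.93, above the log2 limit of 16 of a 16-bit scanner. How the values came to exceed that limit is not given either, so differences are stated as log2 differences on the deposited scale and not as ratios of RNA amounts. The arrays fell into 2 runs. The 9 arrays of experiments 2 to 5 had medians of 4.62 to 4.77 and values with 5 decimals, and the 9 arrays of experiments 7 to 9 had medians of 3.55 to 3.69 and values with 6 decimals. Each run had probe sets with 1 value on all of its own arrays, 162 in the earlier and 238 in the later run, as a normalization of each run by itself leaves them. Each run holds 3 arrays of each group, so group differences are balanced over the runs.

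Probe sets were named from the platform annotation, with 827 symbols brought up to date through their gene identifiers. Of 65770 probe sets that are not controls, 30604 had 1 gene symbol, 2146 had several and 33020 had none. A gene was taken from probe sets with 1 symbol, and for the 355 genes with several such probe sets the one with the highest mean over all arrays was used, which left 30142 genes, 18815 of them protein coding. Of genes with several probe sets that passed the test, 41, 13 and 17 in the comparisons high against negative, low against negative and high against low, another probe set also passed in the same direction for 18, 1 and 3, and none passed in the opposite direction. Tcf7 and Foxj1 had no probe set of their own and could not be tested. No filter on dim genes was applied.

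Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, in 1 fit of all 18 arrays with the group as the only term, and p-values were adjusted by Benjamini-Hochberg over the genes of each comparison, with a threshold of 0.05. The p-values rest on pools of separate experiments as replicates. A second count required a log2 difference of at least 1 in size (at least 2-fold on the deposited scale). Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 87 tests (29 lists with at least 5 measured genes in 3 comparisons), and again with an estimated correlation and with fry, which asks whether a list's genes move on balance in 1 direction. The correlations were estimated from the fit without a block, so they include the offset between the runs. The erythroid markers, with 2 measured genes, were not tested. The 30 lists, which hold 412 different genes of which 378 were measured, the groups, the tests, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes Axin2, Lef1, Tcf7, Nkd1, Lgr5, Notum, Sftpc, Ager, Scgb1a1, Foxj1 and Krt5 in every comparison, the 8 genes with the highest and the 8 with the lowest log2 difference past the threshold in each comparison (above the median of all genes in the higher group, predicted and unnamed loci left out), and up to 3 members of each list called, with the sign of the list. Other list members named below were chosen after their values were seen.

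The labels give each array the number of its experiment, shared by arrays of different groups, so the number marks a shared experiment and pairs the arrays. Residuals from group means of same-numbered arrays correlated across genes at 0.486 to 0.802 in all 16 pairs, and after run means were also removed at −0.147 to 0.410, with 8 of 16 above 0.1. The pairing therefore lies mostly in the run. Because the chosen fit without a block carries the offset of about 1 log2 unit between runs as residual spread, counts with the run as a block are printed beside it. Fits with the experiment as a fixed or random block, each run alone, array centring, quantile normalization over all arrays, a filter on dim genes, other treatments of probe sets, 2 groups at a time, a trended robust variance, array weights and the omission of each experiment were the other settings chosen in advance.

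The tests were run on simulated data of 30142 genes with known changes. For high against negative without a block, 6% of genes changed by 1 log2 unit, 66% of those changed by 2 and 100% of those changed by 4 or 6 were recovered, with 0 unchanged genes called, and with the run as a block 94% of those changed by 1 were recovered, with 10 unchanged genes called. For high against low the shares were 6%, 64% and 100% without a block, and 96% of genes changed by 1 with the run as a block, with 14 unchanged genes called. In 20 draws for high against negative, camera called the list that was moved in 20, but also, on average, 1.3 of 28 unmoved lists without a block and 0 with the run as a block. For low against negative and high against low it called 1.55 and 1.6 unmoved lists without a block. For low against negative, where no change was simulated, it also called the list moved in Wnt-high arrays in 5 of 20 draws, 4 with an estimated correlation and 0 with the run as a block. List calls that end with the run or the experiment as a block are therefore named beside the list. Apart from the run, the simulated genes varied independently, so these rates do not cover lists whose members vary together.

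The depth of an array has no count, and the number of arrays limits the precision. The median of the antigenomic background probe sets was 3.14 on the arrays of experiments 2 to 5 and 2.68 to 2.73 on those of experiments 7 to 9. Between 14830 and 16214 genes lay above the 95th percentile of that background on the earlier arrays, and 11090 to 12209 on the later ones. Where the lower group of a comparison averaged at or below that percentile in at least 1 run, its log2 difference is a lower limit. This held for 939, 431 and 191 of the genes past the threshold for high against negative, low against negative and high against low, and their place in a ranking by size is not fixed. Figures were drawn with matplotlib 3.10.9 and tables prepared with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15. A gene is called near the top of the scale when the mean of the higher group lies within 1 log2 unit of the mean highest array value of that group in at least 1 run, and its difference is then read as a lower limit.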

Results

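Epithelial cells of the mouse lung were sorted into 3 groups by a fluorescent reporter of Wnt/beta-catenin signalling, with high, low or no detectable fluorescence, called Wnt-high, Wnt-low and Wnt-negative here. Each group was measured on 6 arrays, each from a pool of animals of a different experiment. Wnt-high arrays came from experiments 2, 4, 5, 7, 8 and 9, and Wnt-low and Wnt-negative arrays from experiments 3, 4, 5, 7, 8 and 9. Experiments 4, 5, 7, 8 and 9 thus gave an array of every group, which the fit without a block treats as unpaired. Arrays of 1 group within 1 run correlated across the 65770 probe sets that are not controls at 0.987 to 0.993 in Wnt-high, 0.978 to 0.992 in Wnt-low and 0.983 to 0.995 in Wnt-negative. Median log2 values of the arrays were 4.62 to 4.77 in experiments 2 to 5 and 3.55 to 3.69 in experiments 7 to 9.

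The sorted cells had the profile of epithelium in all 3 groups. Cdh1, which encodes E-cadherin, averaged 17.27 ± 0.42 (SD, n = 6 arrays per group here and below) in Wnt-high, 17.02 ± 0.32 in Wnt-low and 16.93 ± 0.41 in Wnt-negative arrays. Epcam, whose product was used for sorting, averaged 10.78 ± 0.93, 10.75 ± 0.96 and 10.71 ± 1.02. Several markers of cells that the depletion should remove were near the array background, with Pecam1 of endothelium at 3.76 ± 0.68, 3.75 ± 0.67 and 3.82 ± 0.67, Tyrobp of myeloid cells at 3.18 ± 0.43, 3.20 ± 0.33 and 3.24 ± 0.43, and Cd3e of T cells at 3.52 ± 0.43, 3.52 ± 0.43 and 3.59 ± 0.42. Col1a2 of fibroblasts was at 3.91 ± 0.67, 3.95 ± 0.72 and 3.93 ± 0.69. Kdr and Esam of the endothelial list were above background in some groups. On the values as deposited, the leading component of variance held 55.9% of it and the next 33.2%. With each gene centred on its run, they held 75.1% and 13.3%, and the 3 groups lay apart from each other on them.

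**Figure D1:**
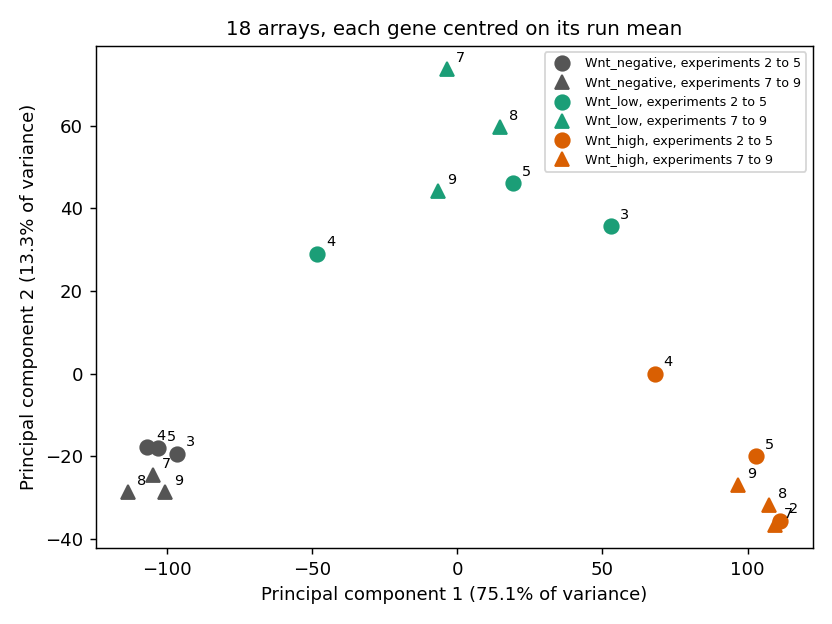
Principal components of the 18 arrays with each gene centred on the mean of its run. The horizontal axis (75.1% of variance) runs from Wnt-negative to Wnt-high arrays, the vertical axis (13.3%) sets Wnt-low arrays apart, and digits beside the points give the experiment.

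Wnt-high and Wnt-negative cells were compared to ask which genes separate epithelial cells with strong reporter signal from those without it. Of 19 ciliated cell markers 17 were higher in the Wnt-high cells, and of 15 alveolar type II markers 14 were lower, the latter list with adjusted p = 0.0600 with an estimated correlation. Cdhr3, a cadherin of ciliated airway cells, averaged 16.98 ± 0.40 in Wnt-high and 6.08 ± 1.35 in Wnt-negative arrays, a log2 difference of 10.90 (SE 0.71, adjusted p = 7.44e-09). Lamp3, a protein of the lamellar bodies that store surfactant, averaged 10.73 ± 2.89 against 17.54 ± 0.29, a log2 difference of −6.81 (SE 1.19, adjusted p = 4.25e-04). Sftpc, the gene of surfactant protein C, was at 19.29 ± 0.60 and 19.29 ± 0.57, close to the highest value of every array, where a difference cannot be read.

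Of 19 measured ciliated cell markers, 17 rose in Wnt-high against Wnt-negative cells (17 also when adjusted over the list alone). The median log2 difference was at least 8.44, a lower limit, since many of these markers were at the background in Wnt-negative arrays in at least 1 run. Rsph1, a radial spoke component, rose by 10.10 (SE 0.68), Tmem212 by 10.77 (SE 0.78) and the dynein heavy chain gene Dnah5 by at least 8.63. Mcidas and Ccno, which act early in the making of multiciliated cells, did not pass, at 4.85 ± 0.76 against 4.66 ± 0.66 and 5.75 ± 1.41 against 6.08 ± 1.80. The list test gave an adjusted p of 2.42e-50, and adjusted p = 0.0137 with an estimated correlation. Of 11 goblet and mucous cell markers, 7 rose (8 adjusted over the list alone), among them Bpifa1 by 8.02 (SE 0.62), Scgb3a1 by 6.96 (SE 0.78) and Bpifb1 by 6.13 (SE 0.71), all secreted airway proteins. That list had adjusted p = 2.44e-11, and adjusted p = 0.0965 with an estimated correlation. Of 12 club cell markers, 5 rose and Aox3 fell by 4.13 (6 and 1 adjusted over the list alone). Scgb1a1, the main secretory product of club cells, rose by 2.26 (SE 0.35), the cytochrome P450 gene Cyp2f2 by at least 3.72 (a lower limit, since it lay near the top of the scale in Wnt-high arrays) and Gabrp by 5.77 (SE 0.70). The club list had adjusted p = 3.70e-04, and adjusted p = 0.274 with an estimated correlation. The neuroendocrine list also rose (adjusted p = 0.00270, and adjusted p = 0.746 with an estimated correlation), but only 2 of its 11 members passed, 4 adjusted over the list alone. They were Uchl1, a deubiquitinating enzyme of neurons and other cells, which rose by 3.78, and Resp18, a protein of secretory granules, by 2.43 (adjusted p = 0.0045, not passing in experiments 2 to 5 alone).

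Of 15 alveolar type II markers, 14 fell in Wnt-high cells (14 adjusted over the list alone), with Sftpc the exception. The complement gene Hc fell by 6.86 (SE 1.23) and Napsa, a protease that processes surfactant protein, by 6.15 (SE 1.15). The median of the list was −4.48. Sftpa1, Slc34a2, Lyz2, Cxcl15 and Sftpb lay near the top of the scale in Wnt-negative arrays, so their falls are lower limits in size. The list had adjusted p = 2.42e-18, and adjusted p = 0.0600 with an estimated correlation. Of 15 alveolar type I markers, 7 fell (11 adjusted over the list alone), among them Ager by 5.32 (SE 0.87), with the water channel gene Aqp5 at −3.39 (SE 0.69) and Vegfa at −3.55 (SE 0.58). Sema3e, a guidance factor on that list, rose by 5.00. The type I list had adjusted p = 9.47e-05, adjusted p = 0.746 with an estimated correlation and adjusted p = 0.0729 with the experiment as a block. Lipid synthesis genes fell with the type II markers, 11 of 15 (11 adjusted over the list alone), with Fads2 lower by a log2 difference of −6.19, the fatty acid synthase gene Fasn at −4.64 and Scd1 at −4.53 (a lower limit in size, near the top of the scale in Wnt-negative arrays), while Dgat2 rose by 2.65. That list had adjusted p = 1.48e-09, and adjusted p = 0.333 with an estimated correlation. MHC class II genes, which present antigen and are expressed by type II cells, fell in 7 of 8 (7 adjusted over the list alone), with H2-Ab1 at −5.27 (SE 1.03) and H2-DMb1 at −4.39 (SE 0.86). The list had adjusted p = 9.80e-07, and adjusted p = 0.333 with an estimated correlation. H2-Eb1, at −4.12, did not pass without experiments 3, 5, 7 or 8 in turn (adjusted p up to 0.144).

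A further 6 lists were called between Wnt-high and Wnt-negative cells, each with 1 to 6 members past the threshold, and none was called with an estimated correlation. Of 19 cell cycle genes, 2 fell (4 adjusted over the list alone, 12 with the run as a block), Mki67 by 3.41 (SE 0.88) and the checkpoint kinase gene Bub1 by 2.18, the latter not passing without experiments 3, 5 or 8 (adjusted p up to 0.103). The list had adjusted p = 0.00195, and adjusted p = 0.863 with an estimated correlation. Of 15 immediate early genes, which respond to stress during dissociation, 3 fell (3 adjusted over the list alone), Jun by 2.06 (SE 0.48), Btg2 by 1.68 (SE 0.34) with Fosb at −2.95, the latter not passing without experiments 8 or 9 (adjusted p up to 0.0571). This list had adjusted p = 0.00458, and adjusted p = 0.847 with an estimated correlation. Among Notch pathway genes, 3 of 12 rose (3 adjusted over the list alone), the effector Hey1 by at least 7.87 and the ligands Jag1 by 2.61 (SE 0.34) and Jag2 by 2.65 (SE 0.52), with adjusted p = 0.00607 for the list, and adjusted p = 0.827 with an estimated correlation. The interferon list rose (adjusted p = 0.00804, and adjusted p = 0.847 with an estimated correlation), although of its 14 members only Usp18, a protease that removes ISG15 and also limits interferon signalling, passed (1 adjusted over the list alone), by 8.27 (SE 0.63). The YAP/TAZ list rose (adjusted p = 0.00755) with 3 of 10 members (3 adjusted over the list alone), Crim1, F3 and Ptpn14 by 6.20, 3.69 and 2.83. F3 encodes tissue factor and Crim1 a membrane protein that binds BMPs. That call was lost at adjusted p = 0.827 with an estimated correlation and at adjusted p = 0.153 with the run as a block. Of 8 antioxidant genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone), Gstm1 by 4.51 (SE 0.35) and Nqo1 by 2.97 (SE 0.34) among the former, Hmox1 with −2.31 and Gclc with −1.64 among the latter. The antioxidant list had adjusted p = 0.00755, and adjusted p = 0.584 with an estimated correlation. When the run was a block, 11 immediate early genes were lower and 1 higher, 5 Notch genes higher and 2 lower, 8 interferon genes higher and 1 lower, 5 YAP/TAZ genes higher and 3 lower, 4 neuroendocrine genes higher, and 3 type I genes higher and 11 lower.

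Among Wnt genes, several feedback genes were lower and a pair of antagonist genes higher in Wnt-high than in Wnt-negative cells. Of 17 measured Wnt/beta-catenin targets and feedback genes, 4 were lower and 2 higher in Wnt-high than in Wnt-negative cells (5 and 2 adjusted over the list alone, 10 and 2 with the run as a block), and the list was not called (adjusted p = 0.121, and 0.202 with the run as a block). Nkd1, a feedback inhibitor of Dishevelled, fell by 5.98 (SE 0.92, adjusted p = 1.22e-04), and Znrf3, a ligase that removes Frizzled receptors, fell by 3.75 (SE 0.57). Bambi fell by 2.87 and Cd44 by 2.60. Wif1, a secreted Wnt antagonist, averaged 11.86 ± 0.33 in Wnt-high, 7.82 ± 1.45 in Wnt-low and 4.98 ± 0.59 in Wnt-negative arrays, and Kremen1, a receptor of Dickkopf inhibitors, was higher by 2.75. Axin2, a general target of the pathway, was at 4.83 ± 1.06 against 6.47 ± 1.10, a log2 difference of −1.64 that did not pass (adjusted p = 0.133) and passed with the run as a block (adjusted p = 1.05e-05), with −1.69 and −1.58 within the 2 runs. The antagonist gene Notum was at 5.05 ± 0.86 against 6.22 ± 1.10, with adjusted p = 0.313, and 1.17e-05 with the run as a block. Both were below the 95th percentile of background in the Wnt-high arrays of experiments 7 to 9, so their differences are lower limits in size. Lef1 (3.12 ± 0.31 and 3.14 ± 0.34) and Lgr5 (3.60 ± 0.54 and 3.57 ± 0.48) were near the background in both groups. Of 23 ligand genes, 3 were higher in Wnt-high cells (3 adjusted over the list alone, 5 higher and 2 lower with the run as a block), Wnt11 by 2.49 (adjusted p = 0.00421), Wnt4 by 2.40 (adjusted p = 0.0290) and Wnt5a by 1.46 (adjusted p = 0.0336), and the latter pair did not pass without some single experiments (adjusted p up to 0.0829 and 0.0937, without experiment 2). Of 17 receptor genes, Fzd4 rose by 2.32 and Fzd3 by 1.63, while Ror1 fell by 4.73 and Lrp5 by 2.72 (3 and 3 adjusted over the list alone, 3 higher and 8 lower with the run as a block). Neither the ligand list (adjusted p = 0.284) nor the receptor list (adjusted p = 0.756) was called.

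**Figure D2:**
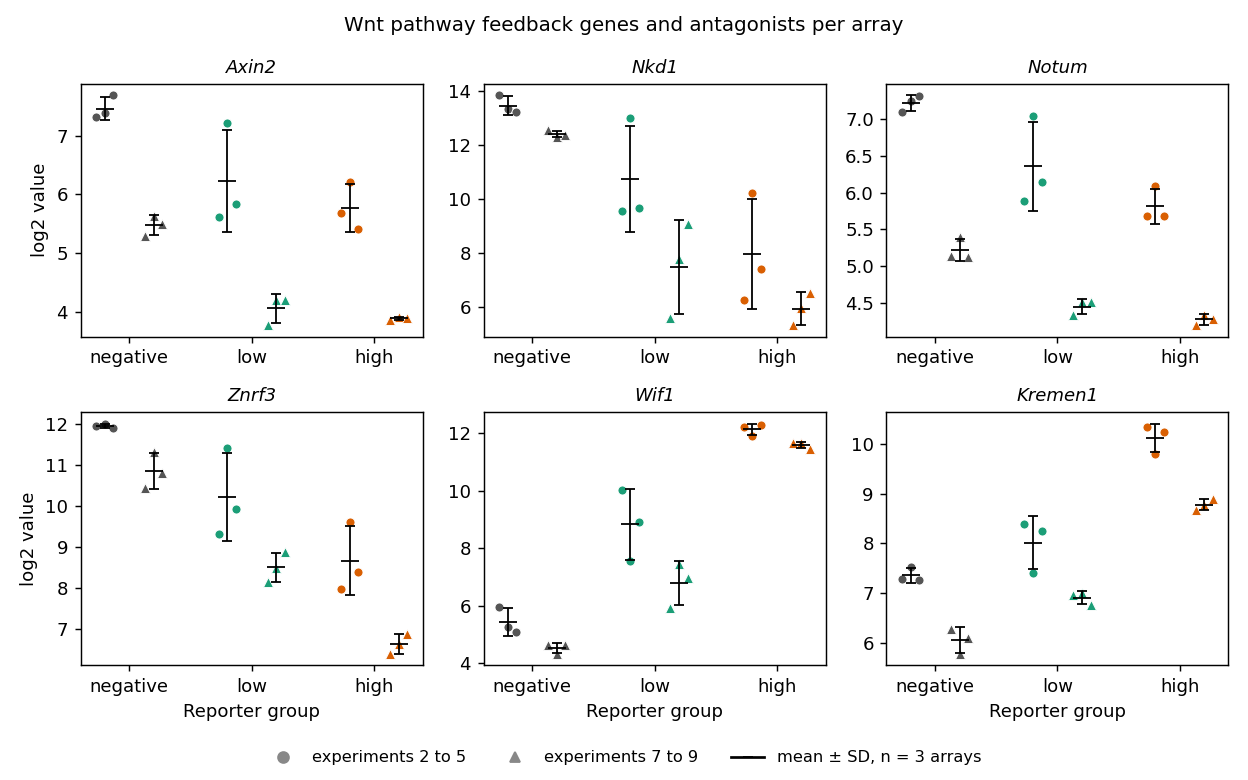
Log2 values of 6 Wnt pathway genes on each array (vertical axis) by reporter group (horizontal axis), with mean and SD of the 3 arrays per run. Axin2, Nkd1, Notum and Znrf3 are highest in Wnt-negative arrays of each run, and Wif1 and Kremen1 are highest in Wnt-high arrays.

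In limma, 2824 of 30142 genes passed between Wnt-high and Wnt-negative cells, 1473 higher and 1351 lower (4556 at an unadjusted p under 0.05). At least 2-fold changes were 2732 of them. With the run as a block 12142 genes passed, 4718 higher and 7424 lower, 11573 passed with the experiment as a block, and 8999 and 7906 passed within experiments 2 to 5 and 7 to 9. All 2824 genes had the same sign in both runs, but they were picked for their mean over both runs, which made a shared sign likely. Log2 differences of all genes correlated between runs at 0.965 across genes, which are not independent replicates. The highest measured differences were those of Spata18 (11.03), Cdhr3, Tmem212, Fam216b (10.73), Rsph4a (10.55), Fam183b (10.34), Igfbp5 (10.29) and Nme5 (10.26). The lowest were those of Itih4 (−7.95), Acoxl (−7.68), Egfl6 (−7.28), Sgpp2 (−6.91), Tinag (−6.88), Hc, Lamp3 and Enpep (−6.57). Since the lower group was at the background in at least 1 run, the differences given for Fam216b, Rsph4a, Igfbp5, Dnah5, Hey1, Usp18, Wif1, Uchl1, Resp18, Nqo1, Sema3e, Dgat2, Fzd4, Wnt11, Wnt4 and Wnt5a, and for Aqp5, Mki67, Bub1 and Ror1 among lower genes, are lower limits in size. Of the 52 named genes that passed, 48 passed without each experiment in turn. With the run as a block all 52 passed, as did all 2824 genes. That block leaves the differences as they are and takes the offset between runs out of the spread, so this was all but certain. The median log2 difference over all genes was −0.0465 here, −0.0286 for low against negative and −0.0131 for high against low.

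Wnt-low and Wnt-negative cells were compared to place the cells of intermediate reporter signal. Of 11 goblet and mucous markers 10 were higher in the Wnt-low cells. Tff2, a trefoil peptide secreted with mucus, was at 16.14 ± 1.07 in Wnt-low and 4.30 ± 0.47 in Wnt-negative arrays, a log2 difference of at least 11.84 (adjusted p = 1.35e-08), as the lower value is at the background. Muc5b, the gel-forming mucin of airways, averaged 15.49 ± 1.38 against 5.11 ± 0.53, a log2 difference of at least 10.38 (adjusted p = 5.05e-08). Scgb1a1 of club cells averaged 18.75 ± 0.20 against 15.59 ± 0.73 (adjusted p = 8.29e-06), with the higher value near the top of the scale.

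Of 11 goblet and mucous markers, 10 rose in Wnt-low cells (10 adjusted over the list alone), with a median of at least 9.23. Bpifb1 was up by 11.57 (SE 0.71) and Scgb3a1 by at least 10.97 (near the top of the scale in Wnt-low arrays). Spdef, a transcription factor of goblet cells, did not pass without a block, at 5.97 ± 0.80 against 5.30 ± 0.88, but did with the run as a block (adjusted p = 1.28e-04), where 11 of 11 were higher. Of 12 club markers, 8 rose (8 adjusted over the list alone), with Gabrp up by 10.40 (SE 0.70), Gsta3 by 4.98 (SE 0.52) and Scgb3a2 by 4.77 (SE 0.47). Both lists had adjusted p = 3.32e-04 with an estimated correlation. Of 19 ciliated markers, 18 rose (18 adjusted over the list alone), with Tmem212 up by 7.89, Cdhr3 by 7.09 and Rsph1 by 6.54. Their median was at least 4.47, again a lower limit, and the list had adjusted p = 0.00708 with an estimated correlation. The Wnt-low arrays of experiments 3 and 4 differed by a median of −3.89 (4 minus 3) in these markers, but without both arrays the ciliated list was still called (run as a block, adjusted p = 3.69e-22). The member not called was Ccno, and Mcidas, at 6.36 ± 1.04 against 4.66 ± 0.66 (adjusted p = 0.0430), did not pass when any experiment was left out (adjusted p up to 0.140). The neuroendocrine list (adjusted p = 0.00607, and adjusted p = 0.784 with an estimated correlation) rested on Uchl1, up by 1.66 (SE 0.30), and Resp18 (2 of 11, 2 adjusted over the list alone). Resp18, up by 2.38, did not pass without experiments 7, 8 or 9 (adjusted p up to 0.120). The mesothelial list (adjusted p = 0.00152, and adjusted p = 0.584 with an estimated correlation) rested on Upk1b, a uroplakin, up by 3.71 (SE 0.49), and mesothelin, Msln, up by 2.80 (SE 0.51), both of which airway epithelium can express (2 of 7, 2 adjusted over the list alone). Wt1, a transcription factor of mesothelium on that list, differed by −0.02.

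A further 6 lists were higher in Wnt-low cells, each with 1 to 3 members past the threshold, and none was called with an estimated correlation. Among transitional alveolar genes, 3 of 11 rose (3 higher and 1 lower adjusted over the list alone), Cldn4 by 4.59 (SE 0.53) and Krt19 by 3.99 (SE 0.41), while Krt8, up by 1.12, did not pass without experiments 5, 7 or 8 (adjusted p up to 0.0863). That list had adjusted p = 0.00607, adjusted p = 0.784 with an estimated correlation and adjusted p = 0.0729 with the experiment as a block. Among 10 epithelial identity genes only the keratin gene Krt18 rose, by 1.11 (SE 0.21, 1 adjusted over the list alone). The list had adjusted p = 0.0359, adjusted p = 0.820 with an estimated correlation and adjusted p = 0.0595 without experiment 7. For high against negative this list was not called without a block (adjusted p = 0.145). With the run as a block it was called there too (adjusted p = 0.00414, 5 higher and 1 lower). Of 14 interferon genes, 3 rose (4 adjusted over the list alone), Usp18 by 4.37 (SE 0.63), Oas1a by 2.13 (SE 0.36) and Ifit1 by 1.72, the latter not passing without experiments 3, 7 or 8 (adjusted p up to 0.115). The interferon list had adjusted p = 2.50e-06, and adjusted p = 0.584 with an estimated correlation. Of 12 Notch genes, Hey1 rose by at least 4.78 and Notch3 by 1.74 (SE 0.33), 2 adjusted over the list alone, with adjusted p = 7.80e-05, and adjusted p = 0.716 with an estimated correlation. Of 8 antioxidant genes, Gstm1 rose by 4.22 (SE 0.35), Gsta4 by 2.44 (SE 0.31) and Nqo1 by 2.30 (SE 0.34), with 3 higher and 1 lower adjusted over the list alone. The antioxidant list had adjusted p = 2.50e-06, and adjusted p = 0.113 with an estimated correlation. Crim1 and F3 of the YAP/TAZ list rose by 4.03 and 3.33 (2 of 10, 3 adjusted over the list alone), with adjusted p = 0.00392, adjusted p = 0.820 with an estimated correlation and adjusted p = 0.0579 with the experiment as a block. Blocked by run, 9 interferon genes were higher, 7 Notch genes higher and 1 lower, 6 antioxidant genes higher and 1 lower, 5 epithelial identity genes and 4 neuroendocrine genes higher, and 4 YAP/TAZ genes higher and 2 lower.

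Of 15 type II markers, 2 fell in Wnt-low cells (7 adjusted over the list alone), Etv5, a transcription factor of type II cells, by 3.78 and the lipid transporter gene Abca3 by 1.83, with a list median of −1.33. Neither passed without experiment 8 in the fit without a block (adjusted p of 0.137 and 0.201). Sftpa1, Slc34a2, Lyz2, Sftpb, Cxcl15 and Sftpc lay near the top of the scale, so their differences may be compressed. The count of lower markers and the median may therefore understate the fall. The list had adjusted p = 1.49e-07, and adjusted p = 0.333 with an estimated correlation. Of 15 lipid synthesis genes, Acaca, Fasn and Hmgcs1 fell by 3.09, 2.60 and 1.86 (8 adjusted over the list alone), with adjusted p = 1.67e-09, and adjusted p = 0.333 with an estimated correlation. Of 8 MHC class II genes, H2-DMb1, H2-DMb2 and H2-DMa, which load peptides, fell by 3.41, 2.75 and 1.97 (7 adjusted over the list alone), with adjusted p = 6.30e-09, and adjusted p = 0.248 with an estimated correlation. Without experiment 8, Acaca, Fasn, Hmgcs1 and H2-DMb1 had adjusted p of 0.0936, 0.166, 0.0547 and 0.138, and H2-DMb2 and H2-DMa reached 0.120 and 0.131 without experiments 7 and 3. Of 15 type I markers, Akap5 fell by 2.23 (SE 0.45) and Emp2 was at −1.40, the latter with adjusted p = 0.0951 without experiment 8, and Sema3e rose by 2.63 (3 lower and 1 higher adjusted over the list alone). The type I list had adjusted p = 0.0480, which ended at adjusted p = 0.965 with an estimated correlation, 0.252 with the run as a block, and 0.0538, 0.109 and 0.102 without experiments 2, 3 and 9. Among Wnt targets, 1 of 17 rose and 1 fell (1 and 2 adjusted over the list alone, 2 and 6 with the run as a block, list adjusted p = 0.0857). They were Wif1, up by 2.83, and Nkd1, with −3.82 (adjusted p = 0.0226, and 0.123 without experiment 8). Axin2 was at −1.32 and did not pass without a block (adjusted p = 0.556), but passed with the run (2.72e-04) or the experiment (4.01e-04) as a block and in experiments 7 to 9 alone (5.38e-04). No Wnt ligand gene passed without a block (2 higher and 3 lower with the run as a block, list adjusted p = 0.703), and among 17 receptor genes Fzd4 (1.34) and Ror1 (−3.38) passed, neither without experiment 8 (adjusted p of 0.268 and 0.109), with list adjusted p = 0.762, and 3 were higher and 5 lower with the run as a block. The block also raised the lower members to 6 type II, 7 type I, 11 lipid and 7 MHC class II genes.

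In limma, 1061 genes passed between Wnt-low and Wnt-negative cells, 840 higher and 221 lower (2515 at an unadjusted p under 0.05), and 1035 of them changed at least 2-fold. Lower calls of the fit without a block, which carries the offset between runs as spread, changed with the omission of single experiments. There were 547 higher and 20 lower genes without experiment 8, 619 and 41 without experiment 5, and 680 and 38 without experiment 3. Without experiment 7 there were 643 and 81, and without experiment 4 782 and 387. In total 660 genes passed without experiment 5 and 567 without experiment 8. With the run as a block 7697 passed, 3713 higher and 3984 lower, and 8002 with the experiment as a block. Within experiments 2 to 5 alone 2532 passed, 1102 of them lower, and within experiments 7 to 9 alone 4471, 1964 of them lower. Lower calls were thus also made in a run that lacks experiment 8. The share of higher calls, 79.2%, was 66.0% of 3792 with arrays centred on their medians and 65.0% of 5148 after quantile normalization. The highest measured differences were those of Tff2, Bpifb1, Scgb3a1, Bpifa1 (10.70), Gabrp, Muc5b, Lypd2 (10.07) and Chad (at least 9.97). The differences given for Usp18, Oas1a, Ifit1, Notch3, Nqo1, Uchl1, Resp18, Msln, Sema3e, Wif1, Fzd4 and Kdr, and for Akap5 and Ror1 among lower genes, are likewise lower limits in size. The lowest were those of Itih4 (−4.60), Acoxl (−4.58), Adam19 (−4.34), Rbpjl (−4.33), Tinag (−4.21), Il33 (−4.12), Lrp2 (−4.06) and Slc24a4 (−4.01). Without experiment 8, in the fit without a block, none of these 8 lower genes passed. Their adjusted p were 0.140, 0.217, 0.0597, 0.116, 0.154, 0.166, 0.0908 and 0.0962. Of the 51 named genes that passed, 30 passed without each experiment in turn. With the run as a block all 51 passed, as did all 1061 genes, which was again all but certain.

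Wnt-high and Wnt-low cells were compared to ask what separates the cells with more and with less reporter signal. Of 19 ciliated markers 17 were higher in the Wnt-high cells, and of 11 goblet and mucous markers 10 were lower. Dnah5, an outer dynein arm chain of motile cilia, averaged 13.22 ± 0.31 in Wnt-high and 8.94 ± 2.10 in Wnt-low arrays, a log2 difference of 4.29 (SE 0.67, adjusted p = 8.96e-04). Muc5b averaged 8.81 ± 2.04 against 15.49 ± 1.38, a log2 difference of −6.68 (SE 0.77, adjusted p = 1.66e-04). Sftpd, the gene of surfactant protein D, averaged 12.45 ± 1.91 against 16.23 ± 0.45 (adjusted p = 0.00106).

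Of 19 ciliated markers, 17 rose in Wnt-high against Wnt-low cells (17 higher and 1 lower adjusted over the list alone), with Hydin up by 4.21 (SE 0.68) and Dnaic1 by 3.94 (SE 0.59), and the list had adjusted p = 0.0489 with an estimated correlation. Of 11 goblet and mucous markers, 10 fell (11 adjusted over the list alone), with Tff2 at −6.63 (SE 0.78) and Bpifb1 at −5.44 (SE 0.71), and adjusted p = 0.00547 with an estimated correlation. Of 12 club markers, 6 fell (8 adjusted over the list alone), among them the paraoxonase gene Pon1 by 5.10 (SE 0.71), Aox3 by 5.03 (SE 0.59) and Gabrp by 4.64 (SE 0.70), with adjusted p = 0.00708 with an estimated correlation, while Scgb1a1 was at 17.84 ± 0.76 against 18.75 ± 0.20 (adjusted p = 0.243, and 0.0493 with the run as a block), near the top of the scale in Wnt-low arrays, so that its difference may be compressed. Of 15 type II markers, 6 fell (14 adjusted over the list alone). Among them were Muc1, by 4.16 (SE 0.57), and Sftpb, by at least 3.10 (near the top of the scale in Wnt-low arrays). Cxcl15, Sftpa1, Slc34a2 and Sftpc also lay near the top of the scale in Wnt-low arrays, so their differences may be compressed. The type II list had adjusted p = 1.12e-17, and adjusted p = 0.0611 with an estimated correlation. Of 15 lipid synthesis genes, Insig1 and Me1 fell, by 2.36 and 2.03 (7 lower and 1 higher adjusted over the list alone), and neither passed without experiment 8 (adjusted p of 0.0874 and 0.0543). Dgat2 rose by 2.08 (adjusted p = 0.0117, and 0.0531 without experiment 7). The lipid list had adjusted p = 6.43e-05, and adjusted p = 0.732 with an estimated correlation. Of 19 cell cycle genes, Mki67 fell by 3.60 (adjusted p = 0.0194, and up to 0.0703 without experiments 5 or 8), 2 fell adjusted over the list alone and 16 with the run as a block, with list adjusted p = 8.21e-06, and adjusted p = 0.784 with an estimated correlation. No immediate early gene passed without a block (2 of 15 lower adjusted over the list alone, 7 lower with the run as a block), and that list had adjusted p = 0.00485, and adjusted p = 0.847 with an estimated correlation. The run as a block also raised the lower members to 9 type II, 10 club and 9 lipid genes.

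A further 4 lists were lower in Wnt-high than in Wnt-low cells in the fit without a block, and each of those calls ended with the run as a block. Of 15 type I markers, 6 fell and Sema3e rose (6 and 1 adjusted over the list alone), with Pdpn at −3.84 (SE 0.59), Aqp5 at −2.99 and Ager at −3.15. Aqp5 had adjusted p = 0.0636 without experiment 8, Ager did not pass without any of experiments 2, 3, 5, 7, 8 and 9 (adjusted p up to 0.187), and Sema3e did not without experiments 4 or 9 (adjusted p up to 0.0690). The type I list had adjusted p = 0.00216, adjusted p = 0.820 with an estimated correlation and 0.143 with the run as a block. Clu and the iron-binding Lcn2 of the transitional list fell by 2.53 and 2.31 (4 lower and 1 higher of 11 adjusted over the list alone), Clu with adjusted p = 0.0732 without experiment 7. That list had adjusted p = 0.0138, adjusted p = 0.820 with an estimated correlation and 0.184 with the run as a block. Upk1b and Msln of the mesothelial list fell by 3.05 and 2.52 (2 of 7 adjusted over the list alone), with adjusted p = 0.0106, adjusted p = 0.746 with an estimated correlation and 0.215 with the run as a block. The chemokine genes Cxcl16 and Ccl20 fell by 3.01 and 2.46 (2 of 15 adjusted over the list alone), with adjusted p = 0.0111 for the cytokine list, adjusted p = 0.847 with an estimated correlation and 0.117 with the run as a block. The Wnt target, ligand and receptor lists were not called (adjusted p of 0.724, 0.319 and 0.865). Wif1 and Kremen1 were higher by 4.05 and 1.99 and Cd44 lower, at −2.16, while no receptor gene passed without a block (4 higher and 6 lower of 17 with the run as a block) and Wnt11 (1.97, adjusted p = 0.0478) did not pass without experiment 4 (adjusted p = 0.160). Blocked by run, 5 Wnt targets were lower and 2 higher, and 3 ligand genes higher and 1 lower.

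In limma, 1351 genes passed between Wnt-high and Wnt-low cells, 721 higher and 630 lower (3030 at an unadjusted p under 0.05), and 1298 changed at least 2-fold. Without experiment 7 there were 861 (494 higher and 367 lower) and without experiment 8 877 (496 and 381), and without experiment 4 461 were higher and 673 lower. With the run as a block 8402 passed, 3451 higher and 4951 lower, and 8139 with the experiment as a block, with 3291 and 6074 within the 2 runs. The highest measured differences were those of A2ml1 (4.79), Slurp2 (4.55), Ldlrad1 (4.43), Drc7 (4.32), Dnaaf3 (4.29), Dnah5, Fam216b (4.25) and Hydin. The lowest, after Muc5b and Tff2, were those of Chad (−6.55), Cyp4a12b (−6.31), Lrrc26 (−5.93), Cyp4a12a (−5.66), the sodium channel subunit Scnn1g (−5.51) and Bpifb1. Cyp4a12a and Cyp4a12b are near-identical copies whose probes cannot be taken as separate. The differences given for A2ml1, Dgat2 and Wnt11, and for Mki67, Aqp5, Msln and Ccl20 among lower genes, are lower limits in size, since the lower group was at the background in at least 1 run. All 35 named genes that passed had the same sign in both runs and passed with the run as a block, which their selection made likely here too. Of these 35 genes, 9 passed within experiments 2 to 5 alone, and 29 passed without each experiment in turn.

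**Figure D3:**
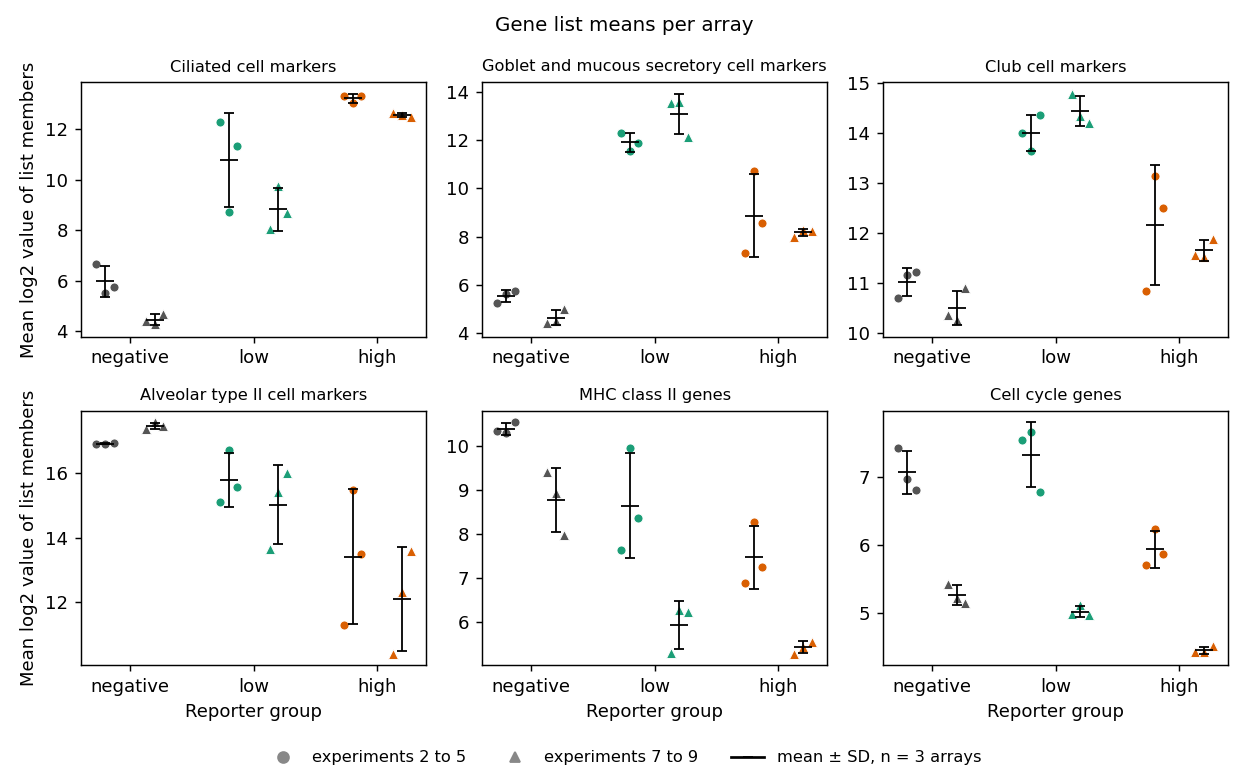
Mean log2 value of 6 gene lists on each array (vertical axis) by reporter group (horizontal axis), with mean and SD of the 3 arrays per run. Ciliated markers rise from Wnt-negative over Wnt-low to Wnt-high arrays, goblet and club markers are highest in Wnt-low arrays, and type II markers are highest in Wnt-negative arrays.

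Genes higher in Wnt-high than in Wnt-negative cells were often also higher in Wnt-low cells. Of the genes called in both comparisons, 621 were higher in both and 214 lower in both, and 1 went opposite ways. Independent lists of these sizes would share 41.0 higher and 9.91 lower genes. In 20 simulations of all arrays without any group difference 0 genes were shared. Hardly any gene passes in such data, so 0 was all but certain there. That count does not measure the overlap that the shared Wnt-negative arrays create. With the run as a block 6003 genes were shared in the same direction, 207 went opposite ways, and independent lists would share 581 higher and 981 lower genes. With the Wnt-negative arrays also split between the comparisons 3907 and 4233 were shared and 83 and 65 went opposite ways. Without experiments 3, 5 and 8 in turn the 835 shared genes were 554, 490 and 432. Of the 621 genes, 483 had the larger difference in Wnt-high cells and 354 were also called higher in Wnt-high than in Wnt-low cells, while 41 were called lower. Of the 214 genes, 208 were lower still in Wnt-high cells, 15 of them called.

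Of 12 endothelial markers, Kdr rose in Wnt-low against Wnt-negative cells by at least 6.01, from 4.57 ± 0.61 to 10.58 ± 0.87, and fell by 4.09 between Wnt-low and Wnt-high cells. Esam fell by 4.26 in Wnt-high against Wnt-negative cells and by 2.92 in Wnt-low cells, the latter not passing without experiments 3, 5, 7 or 8 (adjusted p up to 0.0752). Pecam1 and Cdh5 stayed near background, and the endothelial list was not called (adjusted p of 0.875, 0.820 and 0.252 for high against negative, low against negative and high against low). No myeloid marker of 13, lymphocyte marker of 11 or fibroblast and smooth muscle marker of 15 passed in any comparison without a block, and none of these lists was called (lowest adjusted p of 0.428, 0.714 and 0.752). The 2 measured erythroid markers, Alas2 and Slc4a1, had log2 differences of −0.06 and −0.02 between Wnt-high and Wnt-negative cells. Blocked by run, 1 myeloid marker was higher and 3 lower in Wnt-high than in Wnt-negative cells, and 1 lymphocyte marker higher and 2 lower. In Wnt-low against Wnt-negative cells 1 lymphocyte marker was then lower and 1 fibroblast marker higher, and in Wnt-high against Wnt-low cells 1 myeloid marker higher and 1 fibroblast marker lower. Basal cell markers did not pass in any comparison without a block (10 measured, 1 higher in Wnt-low cells adjusted over the list alone), but with the run as a block 3 were higher in Wnt-low than in Wnt-negative cells, with list adjusted p = 0.0238, and 4 were lower in Wnt-high than in Wnt-low cells, where the list was not called (adjusted p = 0.117). With an estimated correlation and no block the list had adjusted p = 0.973 in every comparison. Krt5 was at 4.56 ± 0.43, 4.98 ± 0.62 and 4.45 ± 0.50 in Wnt-high, Wnt-low and Wnt-negative arrays, with adjusted p = 0.974 for low against negative, and 0.0309 with the run as a block. Without a block the list had adjusted p of 0.822, 0.114 and 0.240 for high against negative, low against negative and high against low.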

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

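No test in this part was chosen after the result was seen, since the rule for single arrays was fixed in advance. Dixon's ratio, the gap of an extreme array to its neighbour over the range of its group, was past its 5% limit in 15 of 330 groups of 6 arrays, where chance flags about 1 in 20 groups, 16.5 here. That rate assumes 1 distribution, while each group mixes 3 arrays of each run with an offset between them, so it is only a rough guide. All arrays were kept, and the cause was not tested for any of these values.

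The Wnt-high array of experiment 4 stood out for 6 genes. Muc5b was high on it, at 12.79 with the nearest array at 8.46 (ratio 0.727), and so was Tff2, at 13.98 against 9.75 (ratio 0.680). Lcn2 was high at 7.46 against 5.82 (ratio 0.744), Msln at 5.53 against 4.26 (ratio 0.705) and Upk1b at 8.44 against 6.49 (ratio 0.633). Fam216b was low on the same array, at 15.56 against 16.23 (ratio 0.698). The Wnt-high array of experiment 2 was low for Scgb1a1, at 16.38 against 17.73 (ratio 0.660), and for Scgb3a2, at 14.02 against 15.64 (ratio 0.757). Nqo1 was high on the Wnt-high array of experiment 5, at 8.15 against 7.26 (ratio 0.781), and A2ml1 was low on that of experiment 9, at 9.44 against 11.25 (ratio 0.769).

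Among Wnt-low arrays, that of experiment 8 was high for Ccl20, at 9.97 against 7.23 (ratio 0.741), and for Msln, at 9.46 against 6.66 (ratio 0.688). Napsa was low on the Wnt-low array of experiment 7, at 9.26 against 14.43 (ratio 0.673). Sftpd was high on that of experiment 4, at 17.08 against 16.30 (ratio 0.644). Itih4 was high on the Wnt-negative array of experiment 7, at 16.88 against 15.70 (ratio 0.647).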

How the results depend on the processing

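No test in this part was chosen after the result was seen, except the fits with the run as a block that left out Wnt-low arrays of experiments 3 and 4 and the fry test with the run as a block, which were added later. Of the named genes that passed in the fit without a block, none changed sign past the threshold in any setting, and 168 of the values across settings no longer passed. Genes that did not pass changed sign in 24 values, all near 0. Counts of genes depended most on whether the run or the experiment was a block. List calls depended most on the correlation, with 33 no longer called with an estimated one and 25 with fry, against 6 with the run as a block. The estimated correlation and that fry test used the fit without a block, so the offset between runs enters them. Fry with the run as a block lost 1 call. An estimated correlation with the run as a block was not tried. Of the named genes, 50 values no longer passed in experiments 2 to 5 alone and 29 without experiment 8. Counts are given for high against negative, low against negative and high against low in this order, and without a block they were 2824, 1061 and 1351 genes and 14, 15 and 11 lists, with 835 genes shared. Leaving out experiment 2 or 3, without a block, unbalanced comparisons with Wnt-high cells over the runs. The median log2 difference over all genes was then −0.148 or 0.0436 for high against negative, and −0.118 or 0.0782 for high against low. With all arrays it was −0.0465 and −0.0131. Changes in those comparisons thus include the offset between runs. Other causes of the changes by left-out experiments were not tested.

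With the experiment as a fixed block, 11573, 8002 and 8139 genes passed, 4196, 2305 and 2793 of them changed at least 2-fold, 7 lists were called for high against low and 6118 genes were shared by the comparisons with negative. Lgr5 differed by −0.01 (high against negative, −0.00918) in that fit. With the experiment as a random block 11451, 8031 and 8248 passed, 4222, 2327 and 2851 at least 2-fold, and Lgr5 differed by −0.00473. With the run as a block 12142, 7697 and 8402 passed, 4188, 2305 and 2742 at least 2-fold, with 7 lists for high against low and 6003 shared genes. Without the Wnt-low arrays of experiments 3 and 4 as well, 12412, 7169 and 8154 passed, 4193, 2352 and 2918 at least 2-fold, with 6 lists for high against low. Over all comparisons 10 list calls ended in that fit, against 6 with the run as a block and all arrays.

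Experiments 2 to 5 alone gave 8999, 2532 and 3291 genes, 4222 at least 2-fold for high against negative and 2065 shared genes. In them Sftpc differed by −0.0198 (high against negative) and Lef1 by −0.0325 (low against negative). Experiments 7 to 9 alone gave 7906, 4471 and 6074 genes, 2156 and 2985 at least 2-fold for low against negative and high against low, and 3301 shared genes. There Lef1 differed by 0.00297 and Lgr5 by −0.0149 (high against negative).

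With arrays centred on their medians 7180, 3792 and 4657 genes passed, 2131 and 2491 at least 2-fold in the comparisons with Wnt-low arrays. Lef1 differed by 0.0468 (high against negative) and Lgr5 by 0.0473 (low against negative). After quantile normalization 8804, 5148 and 5856 passed, 2218 and 2506 at least 2-fold in those comparisons, and 4101 were shared. Lef1 differed by 0.0248 and Sftpc by −0.0274 (high against negative), and Lgr5 by 0.0264 (low against negative). With all probe sets 4531 passed for high against negative, 4357 at least 2-fold. With array weights, whose fit did not fully converge, Lgr5 differed by −0.0261 (high against negative) and Lef1 by −0.0522 (low against negative). Camera with an estimated correlation called 1, 3 and 3 lists, fry 7, 4 and 4, and fry with the run as a block 24 for high against negative and 17 for high against low.

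Leaving out each experiment in turn gave 2298 to 2702, 567 to 1169 and 861 to 1423 genes, 2251 to 2656, 564 to 1159 and 843 to 1387 at least 2-fold, 14 to 15, 14 to 16 and 11 to 13 lists, and 432 to 921 shared genes. Over these fits Lef1 differed by −0.0731 to 0.0358 (high against negative), −0.0237 to 0.0204 (low against negative) and −0.0738 to 0.0349 (high against low). Lgr5 differed by −0.0964 to 0.119 (high against negative) and −0.0722 to 0.143 (high against low). Sftpc differed by −0.112 to 0.155 (high against negative) and −0.146 to 0.0932 (high against low).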

Other observations

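Sox2, a transcription factor of the conducting airways, rose in Wnt-high cells by at least 5.71 and in Wnt-low cells by at least 4.94 against Wnt-negative cells, where it was at the background, at 4.39 ± 0.56 (SD, n = 6). These members were chosen after their values were seen, as were the others of this part. Cebpa, a factor of alveolar type II cells, fell by 2.79 (SE 0.49) and Elf5 by at least 2.35 in Wnt-high against Wnt-negative cells, and Elf5 fell by at least 2.94 against Wnt-low cells. Nkx2-1 and Foxa2 did not pass in any comparison without a block, with 5.86 ± 0.95 and 6.46 ± 0.89 for Nkx2-1 in Wnt-high and Wnt-negative arrays (adjusted p = 1.52e-04 with the run as a block). The list of lung transcription factors was not called (14 measured, 1 higher and 2 lower for high against negative, 3 and 8 with the run as a block, adjusted p = 0.318 for high against negative, 0.714 for low against negative and 0.0713 for high against low).

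Secreted factors differed without a shared direction. Cxcl17, a chemokine of mucosal tissues, rose by 5.73 in Wnt-high and 5.43 in Wnt-low cells, and Il33, an alarmin, fell by 6.49 in Wnt-high cells, with Csf2, which macrophages of the alveoli need, at −3.86. The cytokine list was not called in the comparisons with Wnt-negative cells (adjusted p = 0.202 and 0.875). Bmp4 fell by 2.54 and the matrix protein gene Tgfbi by 4.67 in Wnt-high against Wnt-negative cells, and Id1, a target of BMP signalling, rose by 2.85, with adjusted p of 0.296, 0.541 and 0.400 for that list. Dclk1, a kinase of tuft cells, fell by 2.48 in Wnt-high against Wnt-negative cells, and the kinase gene Bmx of the same list rose by 2.17 in Wnt-low cells. The differences of Csf2, Tgfbi, Dclk1 and Bmx are lower limits in size, as the lower group was at the background in at least 1 run. The tuft list was not called (8 measured, adjusted p of 0.766, 0.705 and 0.203).

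The tests on normalization by run, on type I cells, on exchanged arrays and on free RNA below were chosen after the results were seen, and the others before. Axin2, Nkd1, Notum and Znrf3 were lowest in the cells sorted for the strongest reporter of the same pathway. Their mean difference between Wnt-high and Wnt-negative arrays was −2.97 (SE 0.50) in experiments 2 to 5 and −3.30 (SE 0.16) in experiments 7 to 9. This does not test normalization by run, since each run holds 3 arrays of each group and the genes were picked for the pattern. Whether a smaller share of type II cells accounts for the pattern stayed open. The mean of the 4 genes followed the type II markers over 18 arrays with group and run means removed (Pearson r = 0.786, permutation p = 9.0e-05, adjusted p = 2.7e-04, Spearman rho = 0.893, p = 2.9e-04, r = 0.699 without the 2 most extreme arrays). This does not decide, since the genes were picked for falling from Wnt-negative to Wnt-high arrays, as the type II markers do. Wnt-low arrays also differ along that axis, so other genes with this pattern may follow the markers whatever the cause. The type I markers gave r = 0.704 (permutation p = 4.9e-04, adjusted p = 7.35e-04, rho = 0.738, p = 7.9e-04, r = 0.555 without 2) and the ciliated markers r = −0.581 (permutation p = 0.222, adjusted p = 0.222, rho = −0.412, p = 0.199, r = −0.0157 without 2), of 3 relations tested. Within experiments 2 to 5 and 7 to 9 r was 0.817 and 0.829 for type II and 0.717 and 0.689 for type I markers, so the data do not tell these cells apart, and a signal within each cell type was not measured.

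The Wnt-low arrays of experiments 3 and 4 lay far apart between the Wnt-negative and Wnt-high arrays. Whether cells of the neighbouring gates account for it stayed open. The difference between the 2 arrays correlated at 0.877 across genes (0.901 over bright genes) with that between Wnt-negative and Wnt-high arrays of experiments 7 to 9, but this axis correlated at 0.991 with the component on which the arrays were seen to lie apart, so the value restates the pattern. In experiment 4 the type II markers were higher by a median of 1.21 and the ciliated markers differed by −3.89. The Wnt-high array of experiment 4 also lay nearer to Wnt-negative on that component, at 68.0, with the other Wnt-high arrays at 96.8 to 111. Its Wnt-negative array, at −107, lay within the range of its group. With group and run means removed, the Wnt-high and Wnt-low arrays of experiment 4 correlated at 0.372, and those of experiment 5 at 0.410. The cause was not tested. An exchange of the Wnt-low and Wnt-negative arrays of experiment 4 was excluded, as that Wnt-negative array correlated more with its own group than with Wnt-low arrays, by 0.0464 (mean r of 0.997 and 0.950 over the 30142 genes, a smaller set than the probe sets used for replicate similarity).

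Sftpc was at 1 level in all groups while the other type II markers fell in Wnt-high cells. Whether saturation at the top of the scale accounts for it stayed open. Brighter type II markers fell less (Spearman rho = 0.70 over 15 markers, permutation p = 0.00255, and rho = 0.631, p = 0.00867 over the 14 others). Levels of different probe sets are not strictly comparable, which limits this test. Sftpa1, Slc34a2 and Lyz2 averaged 19.28, 19.28 and 19.11 in Wnt-negative arrays, against 19.29 for Sftpc. They still differed by −2.82, −2.84 and −3.15 in Wnt-high arrays, so the trend with brightness does not by itself account for Sftpc. How far a level lies beyond the top cannot be read. Sftpc was within 0.444 of the highest value among probe sets that are not controls on every array. Against the highest value of all probe sets, its mean gap was 0.503 in the Wnt-low arrays of experiments 2 to 5. The limit of closeness set in advance was therefore met only with control probe sets left out. Free RNA of type II cells in every sort stayed open. The median change of the other markers differed from that of Sftpc by −4.80, but a probe set at the top of the scale cannot show a fall, so this difference does not decide.

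Counts of genes were compared with splits of the arrays into groups that ignore the labels, a test chosen before the result was seen. Of 100 splits without a block, 2, 2 and 3 called as many genes as the labels (the labels included) for high against negative, low against negative and high against low, with the highest other counts at 15146, 15942 and 2357 against 2824, 1061 and 1351. The larger ones followed the run, and the highest count among splits balanced over the runs was 0, 0 and 690. Of 32 splits that part the arrays of every experiment, 1, 1 and 1 called as many, with highest other counts of 0, 0 and 94 without a block and of 5343, 4406 and 2604 with the run as a block, where the labels gave 12142, 7697 and 8402.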
